A study of Homo sapiens with 7 samples.

How the data were processed

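The series held 7 CUT&Tag samples of HCT116, an established human colon cancer cell line, and 6 of them had a peak list that was analysed here. CUT&Tag uses an antibody to tether the Tn5 transposase to chromatin, so that the enzyme cuts and tags the DNA near the bound protein. Per the labels' protocols, 10000 cells went into each assay and the libraries were sequenced on an Illumina instrument. Histone H1 was profiled in 2 wild-type and 2 NuMA-depleted libraries. The sample titles called the depleted libraries AID and the wild-type ones NC, without spelling these out. How far NuMA was depleted cannot be read from the peak lists. Any difference in clone or treatment between AID and NC cells cannot be told apart from depletion. NuMA was profiled in wild-type cells with an antibody to its C terminus and with an antibody to its N terminus, in 1 library each. A control library made with immunoglobulin G had no list and was not analysed here, so no peaks called in it could be set beside the others. The labels did not say whether the replicates came from separate cultures. All p-values between groups therefore measured only the spread between these libraries, which may be technical.

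Per the submitters' processing notes, the authors used Trim Galore, Bowtie2, Picard and MACS2 and the genome build hg19. The notes gave neither versions nor the role of each tool, and these are not given in the sources used here. The deposited files were lists of peaks called per library. Each row gave a start, an end, a score, a fold enrichment, a −log10 p, a −log10 q and the offset of the summit. The score was deposited as a whole number and equalled 10 times the −log10 q without its decimals, and was not used further. The fold was the authors' ratio of fragments to local background at the summit, as deposited. The −log10 p and −log10 q were the authors' values for each peak, and the smallest −log10 q in a deposited list lay between 3.00 and 3.06. The peak names in the lists stated a q limit of 0.001. Each fold is the peak's own value in its own list. It was used to rank, describe and filter peaks within that list, and no change of signal was read directly from folds of different lists. Fragments and background recovered from the fold and the −log10 p were compared between lists in the tests of depth and of summit height. The names of the NuMA peaks called the data ChIP-seq, whereas the labels called them CUT&Tag, and the labels were followed.

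Analyses were run in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. Chromosomes 1 to 22, X and Y were kept. No list repeated a region, so merging rows with several summits changed nothing. Lists were compared by overlap, and 1 bp of overlap counted as shared. Coordinates are 1-based on hg19. Regions shared by lists were counted on the first of them, which was wild-type replicate 1, NuMA-depleted replicate 1 or the C-terminal list. The H1 groups were compared by an exact two-sided permutation test of the library labels, for which 2 against 2 allows no p below 0.333. An overlap was set against 1000 shifts of each peak by 10 to 500 kb within its chromosome, with a one-sided p whose smallest possible value is 0.000999. Shares of peaks carry a standard error (SE) from a jackknife over 5 Mb blocks of the genome. Whether H1 peaks at NuMA sites were kept more or less often was tested with Fisher's exact test, two-sided, and with a logistic model that held the log2 of the lower wild-type fold. Peaks are not replicates, so these tests describe these libraries and not the conditions.

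The deposited lists gave no read totals. The number of fragments at a summit and the local background were recovered from each peak's fold and −log10 p. The fold is the summit count plus 1 over the background plus 1, and the p is the Poisson tail. Between 99.7% and 100.0% of the peaks in a list gave a count within 0.01 of a whole number. The lowest background in a list is the average over the genome. Divided by the shortest peak, which stands for the caller's fragment length, it is proportional to depth. With an assumed genome size of 2.7 Gb it came to 9.77 and 9.76 M fragments for the wild-type H1 libraries, 5.73 and 5.72 M for the NuMA-depleted ones, 2.93 M for the NuMA C terminus and 4.86 M for the N terminus. These totals depend on the assumed size, and their ratios do not. The precision of a call follows from the fragments at a summit, whose median was 15 to 19 in the H1 lists, 27 in the C-terminal list and 58 in the N-terminal list. The recovered background of the NuMA peaks fell on multiples of a fixed step in 56.1% and 66.0% of the peaks tested, against 5.58% to 9.69% in the H1 lists, and the tools' settings behind this difference are not given in the sources used here. Scaled whole counts of a separate control library would fall on such steps, so a control, possibly the immunoglobulin one, may have entered the NuMA calls and not the H1 calls. It stays open whether the NuMA folds, backgrounds and recovered depths rest on such a control.

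The recovery was tested on simulated peaks, of which 100% of 3000 gave back their fragment count. A C-terminal list of 14240 moved peaks overlapped the N-terminal list 1.03 times as often as its shifts did, where 1 was the true value. After 30% of its peaks had been placed on N-terminal peaks, its overlap exceeded the shifts by 26.5 percentage points. In simulations on the 2485 wild-type H1 regions with a true log2 odds ratio of 1, the mean estimate was 0.97 and the 95% interval held the true value in 39 of 40 draws. Thinning of simulated H1 peaks gave 1.00 times the number found by drawing them at the lower depth directly. These simulated peaks had no width, so the check left out the caller's minimum peak length and the choice of a summit.

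Positions named in the text were taken by a rule set before the data were examined, by the lower fold in the lists that had to hold a region. The rule named the 10 highest regions called in both wild-type lists and neither depleted list, in all 4 H1 lists, in both depleted lists and neither wild-type list, and with both NuMA antibodies, and the 5 highest with each NuMA antibody alone. The tables at hand described genes of the assembly GRCh38.p14, a build other than hg19, so no peak was assigned to a gene, promoter, exon or intron. The planned counts by genomic feature and over 20 gene lists were not run for that reason, and the NUMA1 and linker histone genes could not be looked up by position. No list of artefact-prone regions of hg19 was at hand either.

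The alternatives set before the data were examined were a −log10 q of at least 5, H1 lists reduced to the same number of peaks, a reciprocal overlap of 50%, summits within 200 bp, all sequences, removal of each list's top 1% by fold, removal of each replicate in turn, pairing of replicate numbers, NuMA sites of either antibody, loss defined on both depleted lists, and random placement on the chromosome. A −log10 p of at least 15, thinning to the depleted depth and repeats of the named regions under 4 of these settings were added after the data had been seen. The replicate numbers of the H1 libraries were not shown to pair them, since the labels gave a number alone.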

Results

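NuMA is a large structural protein of the nucleus and the mitotic spindle, and histone H1 is the linker histone that binds nucleosomes and the DNA between them. The samples addressed where NuMA lies on chromatin and where histone H1 lies with and without NuMA. The H1 lists held 4552 and 5553 peaks in the wild-type libraries and 2616 and 1480 in the NuMA-depleted libraries on chromosomes 1 to 22, X and Y. The NuMA lists held 14240 peaks for the C-terminal and 19518 for the N-terminal antibody. The recovered depth was 9.77 and 9.76 M fragments in the wild-type H1 libraries and 5.73 and 5.72 M in the depleted ones. The depleted libraries thus had 58.6% of the wild-type depth, and each group had a depth of its own. The NuMA libraries had 2.93 M (C-terminal) and 4.86 M (N-terminal) fragments.

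Fewer H1 regions were called after NuMA depletion. The mean number of H1 peaks was 5052.5 ± 708 (SD, n = 2) in wild-type and 2048 ± 803 (SD, n = 2) in NuMA-depleted libraries, a 2.47-fold difference (log2 ratio −1.30). The covered length was 2147 ± 201.1 kb in wild-type and 866 ± 473 kb in depleted libraries (SD, n = 2, log2 ratio −1.31). Both depleted lists were shorter than both wild-type lists, and the exact permutation test gave p = 0.333 for both measures, the smallest that 2 against 2 libraries can give. With each list reduced to its 1480 strongest peaks the log2 ratio of covered length was −0.21 (exact permutation p = 0.667). Mean peak width was 426 ± 19.9 bp in wild-type and 409 ± 70.7 bp in depleted libraries (SD, n = 2). The log2 ratio of covered length was −0.84 without depleted replicate 2 and −2.01 without depleted replicate 1. Group and depth cannot be told apart in these libraries.

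**Figure D1:**
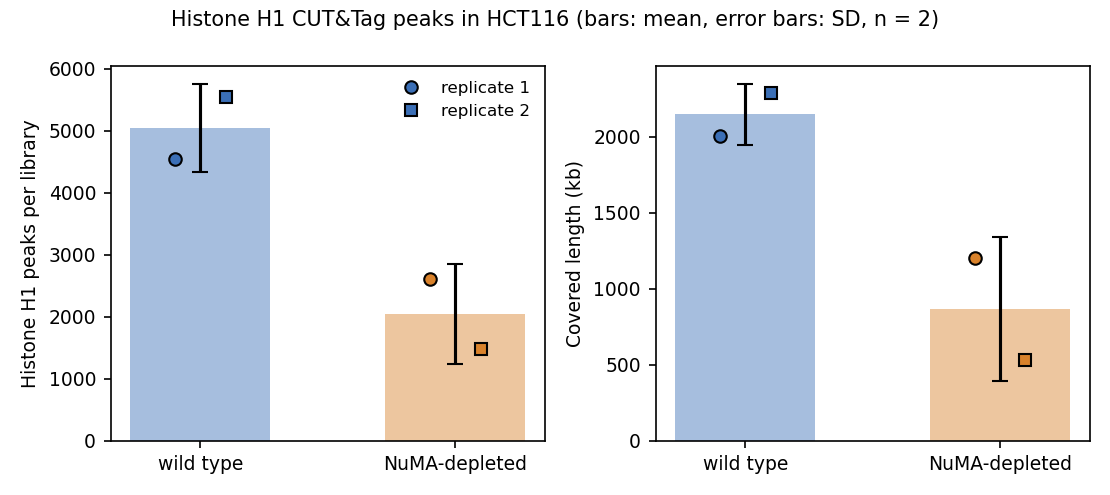
Histone H1 peaks per library (left) and length covered by them in kb (right) in wild-type and NuMA-depleted HCT116 cells, with bars at the mean, error bars of 1 SD and 1 symbol per library (n = 2). The wild-type lists held 4552 and 5553 peaks and the depleted lists 2616 and 1480.

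A part of the H1 regions called in both wild-type lists was not called after depletion. Of the 2485 regions called in both wild-type lists, 594 (23.9% ± 1.2, block SE) were called in both depleted lists, 891 (35.9% ± 0.99) in 1 of them and 1000 (40.2% ± 1.2) in neither. At least 1 depleted list thus held 59.8%, and 77.5% when each list was reduced to its 1480 strongest peaks, which changes both list length and peak strength. In the other direction, 594 (79.7% ± 1.7) of the 745 regions called in both depleted lists were called in both wild-type lists, 109 in 1 of them and 42 (5.64% ± 0.91) in neither. Of all peaks of depleted replicate 1, 60.3% ± 1.2 overlapped wild-type replicate 1 and 60.5% ± 1.1 wild-type replicate 2. The share kept in at least 1 depleted list was 49.2% ± 2.5 in the quartile of lowest wild-type fold and 51.4% ± 2.0 in the second quartile. It was 62.3% ± 2.0 in the third quartile and 76.2% ± 1.7 in the highest quartile. Depleted replicate 1 held 50.5% of the 2485 regions and depleted replicate 2 held 33.1%. Starting from the peaks of 1 wild-type list, 41.8% (replicate 1) and 35.0% (replicate 2) were kept.

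The wild-type libraries also shared only part of their H1 peaks with each other. Wild-type replicate 1 had 54.6% of its peaks in wild-type replicate 2, 34.7% in depleted replicate 1 and 21.5% in depleted replicate 2. Depleted replicate 2 had 50.7% of its peaks in depleted replicate 1, but 66.5% and 68.2% in the longer wild-type lists. Overlap of such lists depends on their length. With each list reduced to its 1480 strongest peaks, the overlap was 46.6% within wild type and 42.7% within the depleted group. Between the groups it was 47.3%, 43.4%, 39.2% and 37.9%, so the 2 pairs within a group lay inside the range of the 4 pairs between groups.

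The H1 regions called in all 4 lists included the peak of highest fold of 3 of the 4 lists. The region on chromosome 9 at 66970988 to 66971556 had folds of 24.9 and 26.1 in wild-type and 22.8 and 27.8 in depleted libraries. A second region on chromosome 9, at 69710750 to 69711304, had 22.4 and 25.6 in wild-type and 20.9 and 23.4 in depleted libraries. These positions lie on the long-arm side of the chromosome 9 centromere, a part of the genome rich in duplicated sequence. The next regions were Y at 59363030 to 59363404 and X at 155260024 to 155260404, both in the pseudoautosomal region at the tip of the long arm, where the X and Y sequences are alike, so that their reads cannot be assigned to 1 of the copies with certainty. The other 6 of the 10 highest lay at 133841529 to 133841879 on chromosome 12, 79947021 to 79947404 on chromosome 5, 167501185 to 167501789 on chromosome 4, 67320398 to 67320948 on chromosome 9, 91852779 to 91853143 on chromosome 1 and 75718097 to 75718740 on chromosome 3, with folds between 14.1 and 23.4. None of these 10 regions overlapped a NuMA peak of either antibody. Artefact-prone regions were not removed, so repeated or copied sequence was not excluded as the source of any of the 10.

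The highest H1 regions called in both wild-type and neither depleted list had wild-type folds between 9.24 and 11.8. The first lay on chromosome 3 at 18336602 to 18337143, with folds of 10.1 and 10.04. It was followed by chromosome 15 at 85131378 to 85131688 (9.64 and 10.2), chromosome 9 at 95640099 to 95640500 (9.87 and 9.63) and chromosome 15 at 79866988 to 79867561 (10.5 and 9.60). The other 6 lay at 151969249 to 151969621 and 109169357 to 109169945 on chromosome 6, 40516826 to 40517327 on chromosome 13, 71446819 to 71447172 on chromosome 8, 65380991 to 65381397 on chromosome 14 and 175395035 to 175395375 on chromosome 5. Of these 10, 3 overlapped an N-terminal NuMA peak and 0 a region called with both antibodies.

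Regions called in both depleted and neither wild-type list were few. The highest of the 42 lay on chromosome 5 at 137667290 to 137667799, with folds of 8.28 and 9.01 in the depleted libraries, and on chromosome 7 at 143169380 to 143169741, with 8.14 and 8.42. Chromosome 2 at 15317348 to 15317749 (8.49 and 7.99) and chromosome 5 at 112312128 to 112312464 (7.95 and 9.20) followed. Of the 10 highest, 2 lay on regions called with both NuMA antibodies, at 41864767 to 41865343 on chromosome 22 and at 127962731 to 127963096 on chromosome 9.

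Peaks of the antibodies to the ends of NuMA overlapped far more often than shifted peaks did. In the C-terminal list, 10398 of 14240 peaks (73.0%) overlapped an N-terminal peak, against 12.5% after shifts within 10 to 500 kb, a 5.85-fold excess. In the N-terminal list, 10030 of 19518 peaks (51.4%) overlapped a C-terminal peak, against 8.97% after shifts, a 5.73-fold excess. Both one-sided p-values were 0.000999, the smallest that 1000 shifts can give. The size of the excess depended on the rule. In the C-terminal list it was 22.96-fold and in the N-terminal list 22.2-fold over random places on the same chromosome. With shifts, the C-terminal excess was 19.2-fold for a reciprocal overlap of 50% and 22.5-fold for summits within 200 bp. With 1 library per antibody these overlaps had no replicate check. No peaks of the immunoglobulin control could be set beside the NuMA lists. Signal that does not depend on the antibody was therefore not tested as a source of the overlap. Shared C-terminal peaks were wider than single ones (median 808.5 against 564.5 bp) but had a lower median fold (4.98 against 6.77). In the N-terminal list, shared peaks were both wider (994 against 645 bp) and of higher fold (5.997 against 4.01).

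The highest region called with both NuMA antibodies lay on chromosome 19 at 1183282 to 1184211, with folds of 28.4 (C-terminal) and 24.8 (N-terminal). Chromosome 2 at 232535761 to 232538242 had 25.9 and 24.8, chromosome 15 at 90753591 to 90754801 had 24.8 and 28.6, and chromosome 1 at 6445289 to 6446418 had 23.7 and 27.1. The other 6 lay at 46195309 to 46196498 on chromosome 19, 66161391 to 66162532 on chromosome 15, 19099489 to 19100350 on chromosome 17, 130716892 to 130717775 on chromosome 9, 184070814 to 184073214 on chromosome 3 and 53440574 to 53442783 on chromosome 12. Of the 10, only the region on chromosome 9 overlapped an H1 peak, in wild-type replicate 1 with a fold of 6.48. Among C-terminal peaks without an N-terminal partner, the highest lay on chromosome 17 at 41919347 to 41920467 (26.4), chromosome 8 at 142047494 to 142048401 (19.6), chromosome 17 at 19091300 to 19092324 (18.96), chromosome 5 at 70070650 to 70072109 (18.96) and chromosome 16 at 85578115 to 85578814 (18.7). Among N-terminal peaks without a C-terminal partner they lay on chromosome 19 at 49645219 to 49646656 (18.98), 8070602 to 8071049 (17.7) and 39847085 to 39847707 (16.9), chromosome 10 at 75474992 to 75475760 (17.4) and chromosome 16 at 67226083 to 67226803 (17.2).

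NuMA peaks were concentrated on a few chromosomes. Chromosome 19, the human chromosome richest in genes for its length, held 8.20 times (C-terminal) and 7.91 times (N-terminal) the peak density of the whole genome. Chromosome 17 held 4.23 and 3.76 times that density, chromosome 22 held 2.98 and 2.72 times and chromosome 16 held 2.77 and 2.63 times. Chromosomes 13 and 18, which are poor in genes, held 0.19 and 0.22 times the mean density in the C-terminal list and 0.28 times in the N-terminal list. Chromosome X held 0.19 (C-terminal) and 0.28 times (N-terminal) and chromosome Y 0.03 times in both lists. Neither gene number nor copy number was tested as a reason for these densities. H1 peaks were spread more evenly, with 1.45 to 1.92 times the mean density on chromosome 19 in the 4 lists. The share of H1 peaks on a chromosome had non-overlapping groups for 8 of 24 chromosomes. It was higher in both depleted libraries on chromosomes 8, 11, X and Y and lower on chromosomes 15, 17, 18 and 20. With 2 against 2 libraries chance alone separates the groups with a probability of 0.333, so 8 of 24 was the number chance gives.

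**Figure D2:**
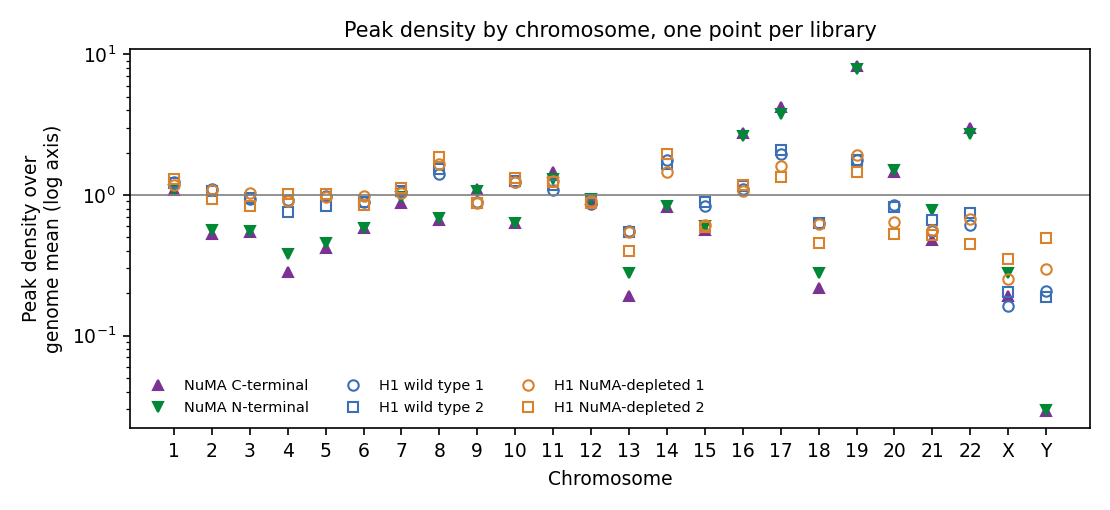
Peak density of each chromosome over the mean density of the genome (log axis) for the 2 NuMA lists (filled triangles) and the 4 H1 lists (open symbols), 1 point per library, with a grey line at 1. Both NuMA lists stood highest on chromosome 19, at 8.20 and 7.91, where the H1 lists lay between 1.45 and 1.92.

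H1 peaks lay at NuMA sites far more often than neighbouring positions did, in wild-type and in depleted cells. Regions called with both NuMA antibodies were overlapped by 14.9% and 11.9% of the wild-type H1 peaks and by 18.2% and 13.4% of the depleted ones. These shares exceeded those of shifted peaks 14.0-fold and 9.91-fold in wild-type and 16.7-fold and 14.6-fold in depleted libraries, each with the smallest possible p of 0.000999. Over random places on the chromosome the excess was 23.7-fold and 18.97-fold in wild-type and 28.6-fold and 24.9-fold in depleted libraries. The mean over the 4 libraries was 13.8-fold with shifts, 38.6-fold for a reciprocal overlap of 50% and 26.2-fold for summits within 200 bp. No peaks of the immunoglobulin control could be set beside these lists. Signal that does not depend on the antibody was therefore not tested as a source of the excess. The mean share was 13.4% ± 2.1 in wild-type and 15.8% ± 3.3 in depleted libraries (SD, n = 2, exact permutation p = 0.667), and a reciprocal overlap of 50% took the difference from 2.37 to −0.051 percentage points. The fold over shifts was 11.97 ± 2.92 in wild-type and 15.63 ± 1.48 in depleted libraries (SD, n = 2, exact permutation p = 0.333, the smallest possible). It was higher in both depleted than in both wild-type libraries, also with sites of either antibody, of the C-terminal or of the N-terminal list. These definitions overlap, and the groups also differed in depth and list length. Most NuMA sites carried no H1 peak. Of the 10398 regions called with both antibodies, 6.54% and 6.36% overlapped an H1 peak of a wild-type list and 4.57% and 1.91% one of a depleted list. The H1 peaks covered only 2005 and 2289 kb in the wild-type and 1201 and 532 kb in the depleted libraries. Calls this sparse cannot show that H1 was absent from a site without a peak. The NuMA lists were both from wild-type cells.

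Whether H1 regions at NuMA sites were kept after NuMA depletion differed between the depleted libraries. Of the 2485 shared wild-type H1 regions, 398 overlapped a region called with both NuMA antibodies. At least 1 depleted list held 65.3% of these 398 and 58.7% of the other 2087 (log2 odds ratio 0.41, Fisher's exact test p = 0.0141). The call ended at a reciprocal overlap of 50% (0.46, Fisher's exact test p = 0.115) and with each list reduced to its 1480 strongest peaks (0.60, Fisher's exact test p = 0.249). It stayed with NuMA sites of either antibody (0.55, Fisher's exact test p = 1.7e-05) and for summits within 200 bp (0.87, Fisher's exact test p = 0.0027). Without each list's top 1% by fold it stayed as well (0.58, Fisher's exact test p = 0.00063). With the wild-type fold in the model the log2 odds ratio was 0.48 ± 0.17 (block SE). The direction rested on depleted replicate 1, which held 58.5% ± 2.5 of the regions at NuMA sites and 49.0% ± 1.4 of the others. Depleted replicate 2 held 28.4% ± 2.6 and 34.0% ± 1.3. With depleted replicate 1 left out the log2 odds ratio was −0.38 ± 0.21 (block SE, Fisher's exact test p = 0.0315) and −0.28 ± 0.21 with the wild-type fold in the model, within 2 block SE of 0 both times. With retention counted only in both depleted lists it was −0.22 (Fisher's exact test p = 0.249). Over all peaks of wild-type replicate 2, with replicate 1 left out, it was 1.11.

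**Figure D3:**
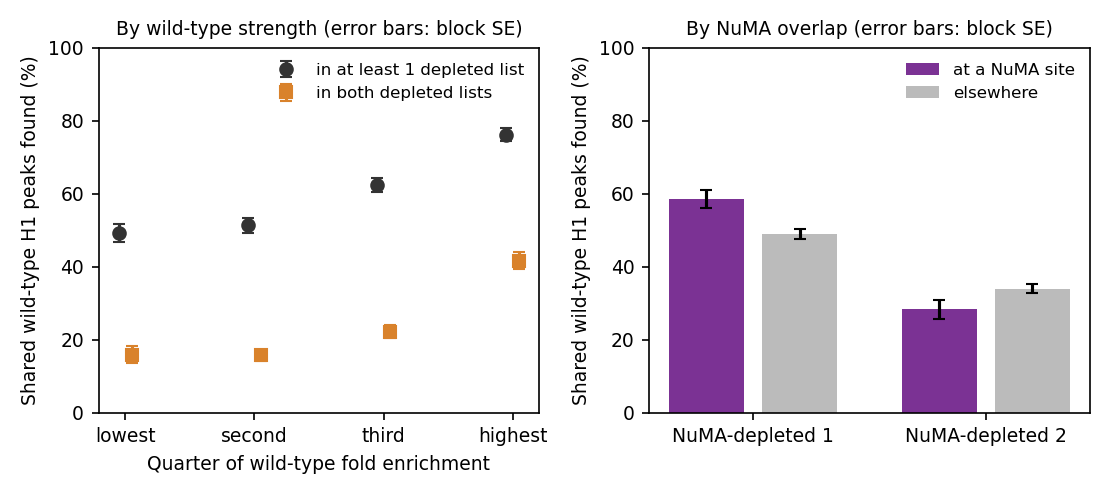
Share (%) of the 2485 H1 regions called in both wild-type lists that were found in depleted lists, by quartile of the lower wild-type fold (left, circles for at least 1 and squares for both depleted lists) and by overlap with a region called with both NuMA antibodies in each depleted library (right). Error bars are block SE. The share in at least 1 list was 49.2% in the lowest and 76.2% in the highest quartile, and regions at NuMA sites and elsewhere were kept in 58.5% and 49.0% in depleted replicate 1 and in 28.4% and 34.0% in depleted replicate 2.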

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

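Peaks on the mitochondrial genome were left out of all comparisons of H1 and NuMA and stood above the limit that a count of 0 allows, which is 3, in 3 of the 6 lists. H1 wild-type replicate 1 had 5 such peaks, H1 wild-type replicate 2 had 6 and H1 NuMA-depleted replicate 2 had 5. The other lists had 3 (H1 NuMA-depleted replicate 1), 1 (NuMA C-terminal) and 0 (NuMA N-terminal), and no list of the immunoglobulin control was analysed to set beside them.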

How the results depend on the processing

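Of 92 cases, 77 left the outcome in place, although the size of a value could still change several-fold. Where there was a p-value this meant the same direction and side of the threshold, and without one the same direction, a value within its spread or a similar count. In 5 a value without a test moved beyond its spread, 2 lost a call and 8 changed sign. Among the 77 were 6 that kept every row and tested nothing, since no list repeated a region, and the comparisons of 2 against 2 libraries could not pass a threshold under any setting. The excess of the NuMA overlap went from 5.85-fold to 19.2-fold for a reciprocal overlap of 50%, 22.5-fold for summits within 200 bp and 22.9-fold over random places on the chromosome, and that of H1 peaks at NuMA sites from 13.8-fold to 38.6-fold, 26.2-fold and 23.9-fold. Lists reduced to the same number of peaks took the log2 ratio of covered length from −1.31 to −0.21 (exact permutation p = 0.667), turned the within-group minus the between-group H1 overlap from −11.2 to 2.69 percentage points, raised the share of wild-type H1 regions kept in at least 1 depleted list from 59.8% to 77.5%, and took the link of kept H1 regions to NuMA to a log2 odds ratio of 0.60 without a call (Fisher's exact test p = 0.249). Fewer regions entered that test. A reciprocal overlap of 50% also ended that call (0.46, Fisher's exact test p = 0.115) and moved the difference between depleted and wild-type shares of H1 peaks at NuMA sites from 2.37 to −0.051 percentage points. Counting only regions kept in both depleted lists turned the log2 odds ratio to −0.22. A −log10 q of at least 5 moved the log2 density of wild-type H1 peaks on chromosome 19 from 0.83 to 0.80. The cause was not tested for these changes, and reduced lists differ in both length and peak strength.

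Without each replicate in turn, the log2 ratio of H1 peak number lay between −1.77 and −0.95, that of covered length between −2.01 and −0.84, the kept share between 33.1% and 50.5%, the log2 odds ratio between −0.38 (without depleted replicate 1) and 1.11 (without wild-type replicate 1), the fold of H1 overlap with NuMA over shifts between 12.7 and 14.998, and the depleted minus wild-type share between 0.02 and 4.73 percentage points. Under the replicate block, which paired replicate numbers, the log2 ratios were −1.35 for peak number and −1.42 for covered length, and the difference in share was 2.37 percentage points, each with a smallest possible exact p of 0.5. For peak number, 5 settings were chosen after the data had been seen. Among peaks of −log10 p of at least 15 the log2 ratio was −1.43, and with the wild-type lists also thinned to the depleted depth it was 0.43, or 0.39 with fragment length scaled too. With 1 fragment added to each summit these became 0.035 and 0.0089, close to 0. Of the 50 named regions, 47 to 50 stayed in their class under 4 settings, also chosen afterwards. Not run were the counts by genomic feature and by gene list, for lack of an hg19 annotation, and peak number at matched list length, which is fixed by construction. Each H1 group had its own depth, so no setting separated group from depth.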

Other observations

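The densest windows of H1 and of NuMA differed, and were singled out after their values had been seen. The 1 Mb window with most H1 peaks was the same in all 4 H1 lists, 86 to 87 Mb on chromosome 8, with 27 and 25 peaks in the wild-type and 19 and 17 in the depleted libraries. The window with most NuMA peaks was 1 to 2 Mb on chromosome 19 in both lists, with 183 (C-terminal) and 229 (N-terminal) peaks. Artefact-prone regions were not removed, and repeats or copy number were not tested as the reason for these dense windows. The recovered depth differed by 0.11% between the wild-type H1 libraries and by 0.12% between the depleted ones, against a 1.71-fold difference between the groups. Whether reads were subsampled to a set number in each group before peaks were called is not given in the sources used here. If they were, the recovered depth is that of the reads used for calling and not of the libraries as sequenced.

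All tests below had their outcomes written down before their results were seen, but the test at a −log10 p of 15 and those of strong sites were designed after the first test of depth. Added only after the results had been seen were 6 readings: the crowding of thinned lists at the calling limit, the limits other than 15, the fragment added to each summit, the unequal size of strong sets, the need for equal list length in the tests of strong sites, and the use of the stronger regions in the test of height. Depth is a candidate explanation for the lower number of H1 peaks after depletion. Wild-type lists thinned to the depleted depth kept a mean of 3601 peaks (3222 to 4004 over 4 pairs, or 2587 to 4591 with fragment length scaled too), against the 2616 and 1480 observed. By depth alone that comparison would argue against depth, but thinning leaves out the caller's minimum peak length. Within 2 units of −log10 p above the limit lay 32.1% to 37.2% of the thinned peaks, against 7.69% to 12.3% in the lists as deposited, so the full count decides nothing. Among peaks of −log10 p of at least 15, the lists thinned by depth held 434 on average (417 to 451 in 4 pairs). With fragment length scaled too they held 445 (265 to 666). All were no more than the 712 of the longer depleted list, next to 455 in the other and 1509 and 1631 before thinning. The values that depth needs were there at this limit, but not under every setting. With 1 fragment added to each summit the thinned lists held up to 593 by depth, above the 455, and up to 868 with fragment length scaled too. In simulations, choosing the summit again after thinning gained 0.082 fragments on average at a peak of mean width and 0.62 at 1 kb. The added fragment thus exceeded that gain. At limits of 10, 12, 20 and 30 the thinned lists by depth held no more than the longer depleted list. With fragment length scaled they held up to 2240 against 1855 at 10, 1392 against 1288 at 12, slightly more than the 121 at 30, and fewer only at 20 (246 against 300). The shorter depleted list had 1075 at 10 and 766 at 12, below the 1482 to 1713 and 856 to 976 of the lists thinned by depth. It had 204 at 20, above their 174 to 189, and 100 at 30, within their 91 to 106. Depth therefore stays open as a cause of both counts, next to NuMA depletion itself and any other difference between the AID and NC cells. Neither depth nor group sets apart the depleted libraries, which had 2616 and 1480 peaks at recovered depths of 5.73 and 5.72 M fragments. What else acted on peak number was not tested. Depth here means that of the reads used for calling, and whether sequencing or subsampling set it is not known.

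Which H1 sites were missing after depletion could not be settled. Of wild-type peaks with a chance of a call of at least 0.95 at the depleted depth, the depleted lists held 57.8% to 72.2%. That chance was too high even between the wild-type lists, where it predicted 98.6% both ways. There, 67.5% of the strong peaks of replicate 1 and 57.2% of those of replicate 2 were found. Those sets were larger and chosen at wild-type depth, so they give no baseline for the depleted lists. The shortfall from 0.95 is therefore no measure of loss. The other wild-type list thinned to the depleted depth held 15.1 percentage points more on average (10.3 to 18.4 in 4 pairs). Thinned lists are longer than the depleted lists, and with the same list length the gap was 5.31 points (2.16 to 10.7), above 5 points in some pairs and below in others. A loss of H1 peaks would itself shorten the depleted lists, so setting list length equal may remove part of such a loss. The smaller gap therefore cannot be credited to depth with list length. Loss of H1 at some sites after NuMA depletion stays open. Variation between the depleted libraries stays open as well. Strong peaks of 1 depleted list were found in the other less often than in thinned wild-type lists, by a mean of −15.4 points, but by between −6.25 and 5.94 points at the same list length. An earlier comparison of strong sets chosen at each target's own depth gave −1.16 points and is void, since it compared sets of unequal size.

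The opposite link of NuMA sites to kept H1 regions in the depleted libraries was not removed by properties of the wild-type peaks. The log2 odds ratios of the depleted lists differed by 0.93 ± 0.21 (block SE) as measured, although that of depleted replicate 2 alone (−0.38 ± 0.21) lay within 2 SE of 0. The difference was 0.90 ± 0.22 with wild-type strength in the model and 0.94 ± 0.24 with peak width as well. The signs were opposite each time. Both properties were nearly alike at NuMA sites and elsewhere, with median folds of 5.98 and 6.17 and median widths of 432.5 and 432 bp. Adjustment for them could therefore change little. An imbalance in either does not account for the opposite signs, and other roles of strength or width were not tested. The depleted libraries differed in shortest peak length (321 and 237 bp), and the part that fragment length plays was not tested. With 2 libraries, no biological explanation was tested.

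C-terminal NuMA peaks of high fold were less often shared with the N-terminal list, against the pattern in the N-terminal list. The share was 93.4% ± 0.45 in the lowest and 61.0% ± 1.4 in the highest quartile by C-terminal fold, but 20.6% ± 0.99 and 77.0% ± 0.83 in the N-terminal list. A low recovered background is a candidate explanation. The 1700 C-terminal peaks at the genome-wide background were shared in 17.4% ± 0.98, against 80.6% ± 0.68 of the others, a difference of −63.1 percentage points. By fragments at the summit the shared part was 23.9%, 74.5%, 94.9% and 98.7% from the lowest to the highest quartile. The fold of a C-terminal peak may thus be high for want of background rather than for many fragments, and that background may come from a control library, if one entered the NuMA calls. Sites bound in a way that only the C-terminal antibody reaches stay open, as untested.

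A loss of H1 at the sites that remained called after depletion was tested as a hypothesis on the 594 regions in all 4 lists. The summit height over the genome background had a median log2 ratio of depleted to wild type of 0.27 on average (0.24 to 0.31 in 4 pairs), above 0 rather than below. A call in a shallower library needs a higher relative height, so the choice of these regions pushes the ratio up. In the stronger regions the ratio was 0.04 to 0.23, against 0.10 between the wild-type libraries. These were chosen by the lower wild-type height, which can in turn pull the ratio down. The test therefore leaves the hypothesis open. Relative height also cannot show a loss that is equal over the whole genome.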
